A study of Felis catus with 12 samples.

How the data were processed

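Primary corneal epithelial cells of 1 cat were plated at 300000 cells, grown for 2 days and serum starved for 6 h in 2% serum, per the labels. Infected cells received FHV-1 at a multiplicity of infection of 10 for 2 h, were rinsed, and then had 2 h in 500 µM raltegravir or DMSO, for collection 4 h after infection. Uninfected cells had the 2 h of raltegravir or DMSO after starvation. From 1 µg of total RNA the authors made poly(A)-selected, strand-specific libraries. There were 4 groups of 3 libraries.

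Per the submitters' processing notes, reads were trimmed with cutadapt 1.8, aligned to the cat genome with TopHat2 2.0.13, assembled with Cufflinks (version not given in the sources used here) and quantified with Cuffdiff 2.2.1. The deposited files, separate for infected and uninfected libraries, hold per library and locus a raw count of fragments, and all raw counts were whole numbers. The deposited FPKM values were scaled by the authors within each table, so they were compared only within a table, as an alternative. The raw fragment counts of both tables cover the same 35078 loci and were scaled again here for comparisons across the tables. The submitters' status was FAIL in 35 entries (26 loci) for infected libraries and in 142 entries (83 loci) for uninfected ones, and these were kept. The 4 other per-sample value columns, which hold fragments scaled internally and externally, were not used here. Viral features are not in the tables.

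Loci were sorted by name into 15803 with a gene symbol, 5164 with an identifier only, 217 merging several genes, 585 antisense to genes and 13309 unannotated. The reference of gene names used here named 0 of 5669 Ensembl identifiers. A merged locus counted for a gene list only if all its symbols were on the list, and each symbol was represented by its locus with the highest mean count. The genome build was not given in the sources used here.

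The depth was the sum of raw fragments, 22198285 to 28551564 in uninfected and 9413461 to 13992323 in infected libraries. PCR copies cannot be told from molecules, so intervals and floors cover counting error only. A group at 0 was compared through a floor of 3 counts over the group, and a group of 1 to 3 counts through an exact Clopper-Pearson 95% interval.

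There were 5 comparisons: raltegravir against DMSO in infected and in uninfected cells, the interaction of raltegravir with infection, and infection in DMSO and in raltegravir. Each used the libraries of its own groups. Loci were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested two-sided by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 and data.table (version 1.17.8). P values were adjusted by Benjamini-Hochberg over all loci of a comparison, with a threshold of 0.05. Gene lists, 33 in number, were fixed before the data were examined, as were the comparisons, the main test and the rule for named genes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

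Genes named are the 10 largest increases and 10 largest decreases per comparison among loci with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM and groups that do not overlap (not asked for the interaction), and the 4 members of each list with the lowest p. With 3 against 3 libraries, groups do not overlap by chance in 10% of cases. Markers of cell types were reported from lists.

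The libraries carry replicate numbers, but the labels do not pair them. Across loci, the deviations of same-numbered libraries correlated at 0.217, 0.0887 and 0.226 for raltegravir in infected cells and at 0.197, −0.0270 and 0.165 in uninfected cells. They correlated at 0.121, −0.0379 and 0.155 for infection in DMSO and at 0.284, 0.162 and 0.220 for infection in raltegravir. For raltegravir in infected cells and for infection in raltegravir, each of the 6 libraries was closest to the one with its own number, and for the other 2 comparisons 4 of 6 were. A fit with the number as a block was an alternative.

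The alternatives were DESeq2 size factors, upper quartiles and library totals for scaling, DESeq2 1.42.0 and limma-voom as tests, a filter of 1 CPM in 3 libraries, all 12 libraries in 1 fit, the replicate block, log2 FPKM with a pseudocount of 1 or 0.1 (FPKM of at least 1 in 3 libraries, or no filter) and leaving out each library in turn. Chosen after the data were seen were scaling and testing without mitochondrial loci, or on nuclear loci with a symbol alone, and thinning all libraries to 9413461 fragments. Other splits of the libraries were refitted: all 10 splits of 3 against 3, and 60 drawn for the interaction.

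The test was tested on simulated data in which 200 loci changed, as many up as down. Many more loci were called in the real data, so the shares below need not hold there. A shift of the scaling was not simulated. At changes of 1.5-, 2- and 4-fold it found 25.4%, 61.2% and 86.4% for raltegravir in infected cells and 53.7%, 71.6% and 87.9% in uninfected cells. It found 5.97%, 41.8% and 69.7% for the interaction, 49.3%, 67.2% and 84.8% for infection in DMSO and 20.9%, 70.1% and 92.4% for infection in raltegravir. Between 3.17% and 8.24% of calls were false, and in each comparison a list of 20 rising loci was called and a list of 20 unchanged ones was not. Simulated loci varied independently of each other, so these lists do not show how the list test behaves for correlated genes. Among real lists, the estimated correlation of oxidative phosphorylation genes was 0.729 for raltegravir in infected cells.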

Results

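Poly(A)-selected RNA was sequenced from primary cells of 1 specific-pathogen-free cat (Felis catus), labelled as corneal epithelial cells, in 4 groups of 3 libraries each. The cells were uninfected or infected with feline herpesvirus 1 (FHV-1, a cause of eye disease in cats), and were treated with raltegravir, an inhibitor of the HIV integrase, or with its solvent DMSO. The labels pose the question of how the drug acts on host transcripts with and without the virus. Infected cells were collected 4 h after infection, of which the last 2 h were in 500 µM raltegravir or DMSO, while uninfected cells had the same 2 h without the preceding 2 h of infection. Infection is therefore compared together with that longer culture. Changes are given as log2 fold change ± SE with 3 libraries per group. The fold change is from edgeR, whose F test gives no SE. The SE is the absolute log2 fold change divided by the square root of F. At low counts this SE can be smaller than the shift from leaving out 1 library, as for NPPC and HIST1H1B below. Levels are given as normalised fragment counts (CPM) ± SD scaled within each comparison. Positions are given as chromosome, start and end, on a genome build not given in the sources used here. The files hold no viral transcripts, so the amount of virus in each library is not known.

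Infected libraries were shallower than uninfected ones. The libraries held 22198285, 28551564 and 25019315 assigned fragments in uninfected DMSO cells and 25723077, 26723091 and 22745114 in uninfected raltegravir cells. They held 11362671, 9522703 and 9413461 in infected DMSO cells and 13992323, 13056727 and 13105791 in infected raltegravir cells. Mitochondrial loci took 3.65% ± 0.202 (SD, n = 3) of fragments in uninfected DMSO cells, 4.03% ± 0.155 in uninfected raltegravir cells, 13.5% ± 0.821 in infected DMSO cells and 8.77% ± 2.26 in infected raltegravir cells. Replicate 2 of infected raltegravir cells, at 11.4%, was the highest of its group. Loci outside annotated genes took 2.77% ± 0.119, 2.62% ± 0.121, 4.69% ± 0.480 and 3.06% ± 0.199 in the same order.

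**Figure D1:**
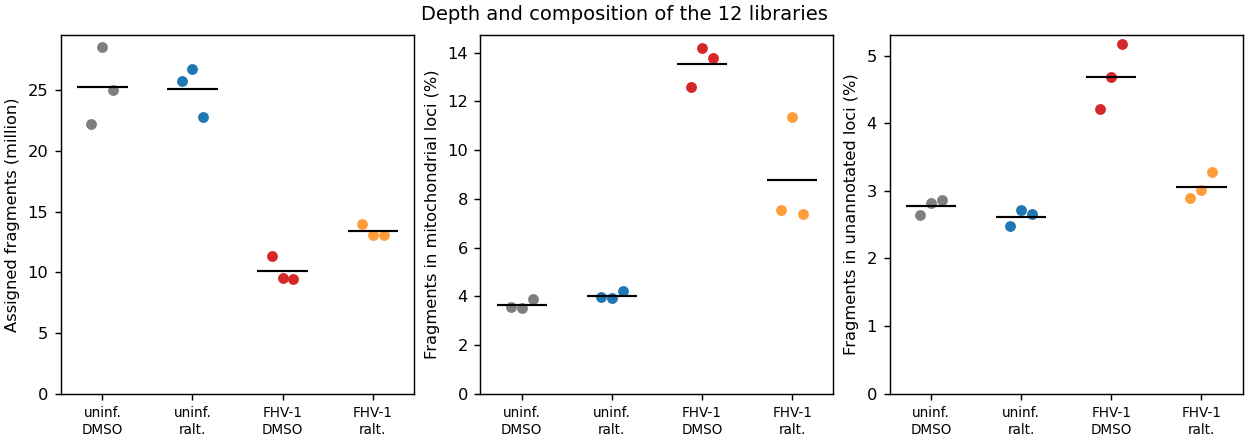
Each point is a library and each horizontal line a group mean, for assigned fragments and for the percent of fragments in mitochondrial loci and in loci outside annotated genes. Infected DMSO cells had the smallest totals (9413461 to 11362671 fragments) and the highest mean mitochondrial share (13.5%).

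The most abundant marker transcripts of the uninfected DMSO cells were stromal. Of 22 listed markers of stromal keratocytes and fibroblasts, 20 had a locus and 18 reached 1 CPM, with a median of 1474 CPM. COL1A1, a chain of type I collagen, was at 15782 ± 1203 CPM and the matrix protein gene SPARC at 5531 ± 201 CPM. Of 24 listed markers of corneal epithelium, 18 had a locus and 6 reached 1 CPM, with a median of 0.189 CPM. The integrin gene ITGA6 was at 39.5 ± 1.91 CPM and PERP at 23.3 ± 2.91 CPM. PAX6, a transcription factor of the eye, was at 2.09 ± 0.348 CPM, while the keratin genes KRT12 and KRT5 were at 0.103 and 0.0134 CPM. These levels go against the epithelial label, which is used here only as the name of the cells. Of the markers listed for immune cells 2 of 18 with a locus reached 1 CPM, for melanocytes and Schwann cells 2 of 8, and for vascular endothelium 4 of 11.

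In DMSO, infection raised ATF3, FOS and HIST1H1B and lowered CXCL8, LIF and CTGF. ATF3, a stress-induced transcription factor (chromosome F1, 30445076 to 30460441), rose by 4.40 ± 0.13, from 25.4 ± 4.96 to 534 ± 53.01 CPM (adjusted p = 8.92e-18). FOS, a subunit of AP-1 (chromosome B3, 121635729 to 121639149), rose by 4.57 ± 0.13, from 4.89 ± 1.30 to 115 ± 4.59 CPM. The linker histone gene HIST1H1B (chromosome B2, 2687715 to 2692393) rose by 7.62 ± 0.19, from 0.497 ± 0.351 to 94.96 ± 9.84 CPM, and by 8.25 without uninfected DMSO replicate 1. The chemokine gene CXCL8 (chromosome B1, 145951818 to 145955733) fell from 1296 ± 4.44 to 220 ± 61.6 CPM, a log2 change of −2.56 ± 0.14. The cytokine gene LIF (chromosome D3, 21473100 to 21482034) fell from 258 ± 7.28 to 34.7 ± 14.4 CPM, and CTGF, a secreted target of the coactivator YAP (chromosome B2, 121190773 to 121193226), from 672 ± 39.6 to 120 ± 18.0 CPM. The other large increases were in H2BFS, HIST1H2BI, TRIM72, HIST1H1A, PCDH17 and SEPT4, from 4.36 to 5.70, and the other large decreases in HAS2, HTR1B, CCL2, IRS1, FBXL4, CSF3 and PLEKHF1, from −2.66 to −2.31.

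The natriuretic peptide gene NPPC had 1 fragment in the 3 uninfected DMSO libraries and 359 in the 3 infected DMSO libraries, a ratio of 898 with an exact Clopper-Pearson 95% interval from 160 to 35557. Its fitted change of 9.36 ± 0.40, which became 10.69 without uninfected DMSO replicate 3, depends on the prior count. FAM71A had 0 fragments in uninfected DMSO cells and 271 in infected DMSO cells. The exact Clopper-Pearson 95% interval of the ratio starts at 182, and against a floor of 3 counts over the group the ratio was 226. The intervals and the floor cover counting error only.

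Of 18284 loci tested for infection in DMSO, 6638 were higher and 5959 lower after Benjamini-Hochberg adjustment over all loci. Among loci with a gene symbol 2234 were higher and 4311 lower, and 4406 higher and 1991 lower loci changed at least 2-fold. This balance depends on the scaling: scaled on nuclear loci with a symbol alone, 3201 were higher and 3248 lower. Loci outside annotated genes moved together, but that scaling leaves out other kinds of locus too, so the cause was not tested. Scaling by upper quartiles moved the median of all loci to 0.142, and scaling by library totals to −0.177.

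**Figure D2:**
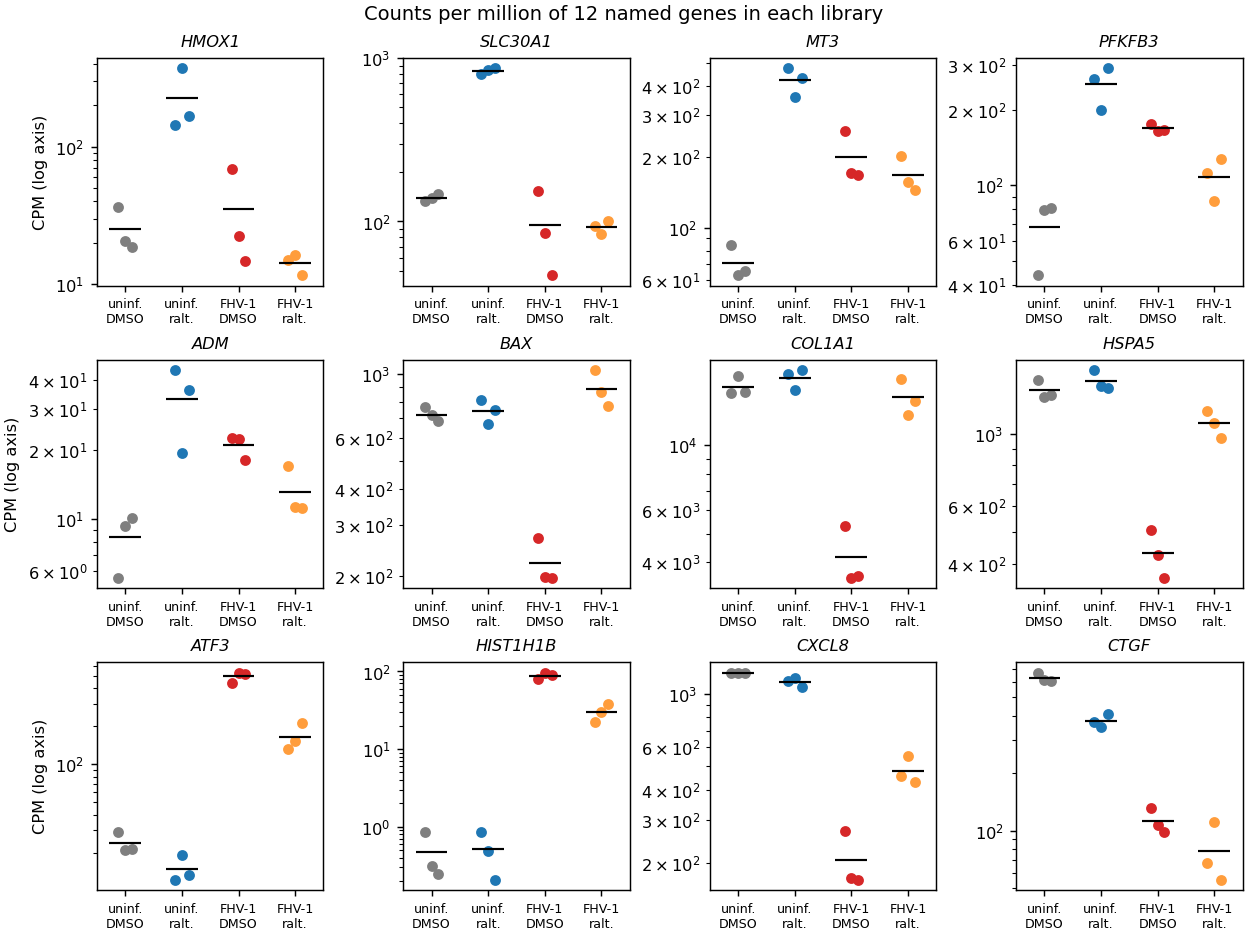
Points are the CPM of each library on a log axis for 12 named genes in the 4 groups, and lines mark group means. ATF3 and HIST1H1B rose with infection and SLC30A1 and HMOX1 rose with raltegravir in uninfected cells only, while BAX and COL1A1 fell with infection and were higher with raltegravir in infected cells.

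Replication-dependent histone genes showed the strongest list-wide increase with infection, with 13 of 15 tested members higher, 2 lower and a median of 3.67 (adjusted p = 2.85e-15, and 0.56 with an estimated correlation). Because the libraries were poly(A)-selected, the histone changes with infection or raltegravir cover polyadenylated transcripts only, and total histone RNA was not measured. Ribosomal protein genes rose in 38 of 45 cases and fell in 1, including RPS13 by 1.44 ± 0.09 and RPS15A by 1.36 (adjusted p = 5.31e-07, and 0.693 with an estimated correlation). Targets of YAP, which relays cell contact and tension, fell in 13 of 16 cases with none higher, including CTGF by −2.49 ± 0.11 and AMOTL2 by −1.97 (adjusted p = 8.93e-06, and 0.586 with an estimated correlation). NF-kB and inflammatory genes fell in 16 of 23 cases and rose in 3, with CXCL8, CCL2 and LIF among the lower ones (adjusted p = 0.000302, and 0.586 with an estimated correlation). Genes of the G1/S transition and DNA replication fell in 26 of 36 cases and rose in 1, including the helicase subunit MCM6 by −1.18 (adjusted p = 0.000208, and 0.693 with an estimated correlation). Genes of G2/M and mitosis fell in 20 of 32 cases and rose in 2, including CENPF by −1.50, while CKS2 rose by 1.22 (adjusted p = 0.000302, and 0.693 with an estimated correlation).

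Apoptosis regulators fell in 13 of 21 cases and rose in 3, and the pore-forming BAX fell by 1.69 ± 0.11 on the log2 scale (adjusted p = 0.0135, and 0.586 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 11 of 21 cases and rose in 3, including HSPA5 by −1.64 ± 0.11, while CALR rose by 1.04 (adjusted p = 0.0153, and 0.754 with an estimated correlation). Stromal markers fell in 9 of 19 cases and rose in 3, including COL1A1 by −1.91 ± 0.14 and THY1 by −1.56 (adjusted p = 0.0231, and 0.693 with an estimated correlation). ATF4 and integrated stress genes fell in 14 of 27 cases and rose in 6, with the transcription factor gene DDIT3 up by 2.27 and CHAC1 down by −2.01 (adjusted p = 0.0495, and 0.693 with an estimated correlation). TGF-beta targets fell in 11 of 16 cases and rose in 4, with ID1 at −1.83 and ID2, an inhibitor of differentiation, at 3.05 (adjusted p = 0.0495, and 0.586 with an estimated correlation). The calls of these last lists depended on the libraries used: without infected DMSO replicate 3 the adjusted p was 0.0571 for both ATF4 genes and TGF-beta targets, and without infected DMSO replicate 2 it was 0.0586 for TGF-beta targets. Over all alternatives tried with the preset correlation it ran from 0.0158 to 0.101 for ATF4 genes and from 0.0212 to 0.101 for TGF-beta targets. All 4 tested loci on the list of mitochondrially encoded genes, chosen by name, rose, too few for the list test.

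Immediate-early genes as a list had no call with infection (9 higher and 14 lower of 24, adjusted p = 0.146), and neither had interferon-stimulated genes (9 higher and 2 lower of 27, adjusted p = 0.866), of which IRF9 rose by 0.85 and the antiviral MX1 by 1.55. Nuclear genes of oxidative phosphorylation had 17 higher and 17 lower of 51, with a median of −0.07, a mean of 0.02 and a list test pointing downward (adjusted p = 0.701). Adjusted over the list alone, the counts were unchanged for the 11 called lists except stromal markers (2 higher) and TGF-beta targets (5 higher). Of 29 lists tested, 11 were called with the preset correlation and 0 with an estimated correlation.

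In uninfected cells, raltegravir raised SLC30A1, MT3, HMOX1 and PFKFB3 and lowered HAS2. SLC30A1, a zinc exporter (chromosome F1, 31300610 to 31308020), rose by 2.53 ± 0.07, from 155 ± 6.48 to 897 ± 41.3 CPM (adjusted p = 1.95e-09). The metallothionein gene MT3 (chromosome E2, 36008354 to 36039341) rose by 2.53 ± 0.13, from 78.5 ± 13.4 to 452 ± 59.3 CPM, though fragments of related metallothioneins cannot be told from its own in these counts. HMOX1, the inducible heme oxygenase (chromosome B4, 131883838 to 131891651), rose by 3.15 ± 0.34, from 27.8 ± 10.8 to 244 ± 135 CPM (adjusted p = 0.000499). PFKFB3, a regulator of glycolysis (chromosome B4, 5425496 to 5464525), rose by 1.84 ± 0.20, from 75.3 ± 23.1 to 270 ± 50.7 CPM. The hyaluronan synthase gene HAS2 (chromosome F2, 64475136 to 64505681) fell from 95.7 ± 17.6 to 36.4 ± 7.49 CPM, a log2 change of −1.40 ± 0.15. The other large increases were in ADM, RAB3A, SPRY1, PPP1R3B, NFKBIZ and DDIT4, from 1.28 to 1.93, and the other large decreases in C17orf80, LSM11, TM4SF18, KBTBD8, RSRP1, PHLDA1, MAT2A, LENG8 and ZBTB9, from −1.34 to −1.10. Of these 20 genes 18 lost their call in log2 FPKM with no filter, and SLC30A1 and MT3 kept theirs under all alternatives. On counts only DDIT4 lost its call, without uninfected DMSO replicate 2 (adjusted p = 0.0589) and without uninfected raltegravir replicate 3 (adjusted p = 0.0561), with a range from 3.55e-09 to 0.198 over its alternatives.

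Of 17579 loci tested in uninfected cells, 700 were higher and 699 lower with raltegravir, and among loci with a symbol 359 were higher and 363 lower. This count rested on single libraries: it was 686, 477 and 490 without uninfected DMSO replicates 1, 2 and 3, 2820 without uninfected raltegravir replicate 2 and 433 without uninfected raltegravir replicate 3. Libraries scaled by totals alone gave a higher share of 36.8% in place of 50.04%.

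Genes of hypoxia and glycolysis rose in 11 of 23 cases with none lower, and in 17 adjusted over the list alone (adjusted p = 1.42e-16, and 0.488 with an estimated correlation). They included the oxygen sensor EGLN1 (1.17 ± 0.09), the hexokinase HK2 (0.89 ± 0.12) and PDK1 (0.60 ± 0.08). Metal homeostasis genes had 3 higher and 1 lower of 16, and 4 higher and 1 lower adjusted over the list alone (adjusted p = 6.02e-11, and 0.28 with an estimated correlation). Genes of cholesterol synthesis had 4 higher and 0 lower of 24, with the sterol sensor partner INSIG1 at 1.08 ± 0.21 (adjusted p = 0.0561 without uninfected DMSO replicate 3, and from 5.86e-08 to 0.175 over its alternatives), and 7 higher adjusted over the list alone (adjusted p = 0.000196, and 0.898 with an estimated correlation). TGF-beta targets had 3 higher and 0 lower of 16 by either adjustment, including ID2 at 1.25 ± 0.09 (adjusted p = 0.00286, and 0.488 with an estimated correlation). Immediate-early genes had 2 higher and 7 lower of 24, including IER2 at −0.77 and NR4A2 at 0.53, and 4 higher and 7 lower adjusted over the list alone (adjusted p = 0.0312, and 0.898 with an estimated correlation). Targets of p53 had 1 higher and 6 lower of 20, including the higher TP53INP1 at 0.54, and 1 higher and 9 lower adjusted over the list alone, but 1 higher and 1 lower with all 12 libraries in 1 fit (adjusted p = 0.0312, and 0.865 with an estimated correlation). Genes of xenobiotic response had 1 higher of 10, TIPARP at 1.11 ± 0.08 (adjusted p = 0.0312, and 0.488 with an estimated correlation), and stromal markers 1 higher of 19, ZEB1 at 0.57 (adjusted p = 0.0312, and 0.898 with an estimated correlation), each by either adjustment.

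The calls of 4 of these lists depended on 1 library or more. Those of immediate-early and xenobiotic response genes were also lost with limma-voom. That of stromal markers was also lost with library totals and with a filter of 1 CPM in 3 libraries. Immediate-early genes had an adjusted p of 0.464 without uninfected DMSO replicate 1 and 0.524 without uninfected raltegravir replicate 2 (0.0016 to 0.524 over all alternatives). Targets of p53 had 0.117 and 0.0549 without uninfected DMSO replicates 1 and 3 (0.00209 to 0.117). Xenobiotic response genes had 0.0598 and 0.0706 without uninfected DMSO replicates 2 and 3 and 0.106 without uninfected raltegravir replicate 2 (0.00459 to 0.157). Stromal markers had 0.0582 without uninfected DMSO replicate 3 and 0.129 and 0.101 without uninfected raltegravir replicates 1 and 3 (0.0016 to 0.129). Oxidative phosphorylation, chaperones of the endoplasmic reticulum, heat shock and interferon-stimulated genes had 0 members called of 51, 21, 17 and 28, and the median and mean of interferon-stimulated genes differed in sign (0.00643 and −0.00523). At an unadjusted p under 0.05 edgeR gave 0, 4, 2 and 1 of them, DESeq2 called 0, 2, 0 and 1, and limma-voom 0, 2, 0 and 1. Of 29 lists tested, 8 were called with the preset correlation and 0 with an estimated correlation.

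In infected cells, BAX, COL1A1 and TGFBI were higher and RGS16, ATF3 and HIST1H1B lower with raltegravir. BAX (chromosome E2, 8362490 to 8370296) was higher by 1.94 ± 0.16, at 208 ± 39.4 CPM in DMSO and 800 ± 110 CPM in raltegravir (adjusted p = 1.14e-05). COL1A1 (chromosome E1, 37439116 to 37465308) was higher by 1.75 ± 0.19, at 3891 ± 965 and 13099 ± 1754 CPM. TGFBI, an extracellular matrix protein of the cornea (chromosome A1, 113241627 to 113292736), was higher by 1.59 ± 0.12, at 41.7 ± 3.04 and 125 ± 6.60 CPM. RGS16, a regulator of G protein signalling (chromosome F1, 25200426 to 25206517), was lower by a log2 change of −2.01 ± 0.18, at 20.8 ± 1.66 and 5.15 ± 0.801 CPM. ATF3 was lower by −1.64 ± 0.16, at 466 ± 43.8 and 149 ± 36.9 CPM (adjusted p = 2.15e-05), and HIST1H1B by −1.62 ± 0.17, at 82.8 ± 8.20 and 27.0 ± 7.21 CPM. The other large increases were in TMEM54, CCDC160, CINP, APOLD1, UROS, ST3GAL2 and TMTC2, from 1.58 to 1.76, and the other large decreases in EGR3, FAM71A, HIST1H1A, FOSB, NPPC, HIST1H1T and SEPT4, from −1.76 to −1.53. SEPT4 lost its call in log2 FPKM with no filter.

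Of 16240 loci tested in infected cells, 3862 were higher and 3887 lower with raltegravir. Among loci with a symbol 3083 were higher and 1394 lower, and 662 higher and 2173 lower loci changed at least 2-fold. Scaled on nuclear loci with a symbol alone, 1995 were higher and 2227 lower. Scaling by upper quartiles moved the median of all loci to −0.158 and gave a higher share of 37.1%, and library totals moved it to −0.241 with a higher share of 30.1%, against 49.8% in the main scaling. Without infected DMSO replicate 3 the count called was 4887.

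Nuclear genes of oxidative phosphorylation were higher with raltegravir in 35 of 51 cases with none lower, and in 36 adjusted over the list alone (adjusted p = 2.45e-09, and 0.817 with an estimated correlation). UQCRB of complex III was higher by 1.35 ± 0.15, NDUFA12 of complex I by 1.34 ± 0.17 and SDHB of complex II by 1.10 ± 0.16. Immediate-early genes were lower in 18 of 24 cases with none higher, and in 20 adjusted over the list alone, including FOS by −1.08 ± 0.13 and DUSP1 by −1.11 ± 0.12 (adjusted p = 2.45e-09, and 0.598 with an estimated correlation). Stromal markers were higher in 13 of 19 cases with none lower, and in 14 adjusted over the list alone, including THY1 by 1.36 ± 0.13 (adjusted p = 1.35e-07, and 0.535 with an estimated correlation). Histone genes were lower in 11 of 14 cases and higher in 1 by either adjustment (adjusted p = 7.95e-07, and 0.535 with an estimated correlation). Chaperones of the endoplasmic reticulum were higher in 15 of 21 cases and lower in 3, and in 16 and 3 adjusted over the list alone, with HSP90B1 at 602 ± 78.3 CPM in DMSO and 1637 ± 152 CPM in raltegravir (adjusted p = 0.000199, and 0.655 with an estimated correlation). Genes of cholesterol synthesis were higher in 13 of 24 cases and lower in 1 by either adjustment, including FDPS by 1.15 ± 0.13 (adjusted p = 0.000568, and 0.817 with an estimated correlation).

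Genes of MHC class I presentation were higher in 5 of 8 cases and lower in 1 by either adjustment, including B2M by 1.29 ± 0.17 (adjusted p = 0.00334, and 0.598 with an estimated correlation). Genes of G2/M and mitosis had 11 higher and 3 lower of 32 by either adjustment, including CENPA at 0.98 (adjusted p = 0.0198, and 0.929 with an estimated correlation). Heat shock genes had 8 higher and 2 lower of 17, and 9 and 2 adjusted over the list alone, including the chaperone HSP90AB1 at 1.00 (adjusted p = 0.0281, and 0.817 with an estimated correlation). Ribosomal protein genes had 17 higher and 1 lower of 45 by either adjustment, including RPL37A at 1.01 (adjusted p = 0.0441, and 0.929 with an estimated correlation). The ribosomal call was lost without infected DMSO replicate 3 (adjusted p = 0.0956) and without infected raltegravir replicate 1 (0.701), with a range from 0.000736 to 0.701 over all alternatives. The heat shock call was lost with library totals (0.0713), with a range from 0.00592 to 0.0713, and the ribosomal and G2/M calls with library totals as well (0.146 and 0.0606), and the ribosomal call with a filter of 1 CPM in 3 libraries (0.0685). The G2/M call was also lost without infected DMSO replicate 3 (0.0612) and without infected raltegravir replicate 2 (0.0793), with a range from 0.00118 to 0.0793.

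MAPK output genes had 1 higher and 6 lower of 14, including the phosphatase DUSP5 at −1.37 ± 0.16, without a list call (adjusted p = 0.0506). Genes of hypoxia and glycolysis had 12 higher and 5 lower of 23 (adjusted p = 0.142), and NF-kB and inflammatory genes 2 higher and 9 lower of 21 (adjusted p = 0.206). Metal homeostasis genes had 5 higher and 4 lower of 16, a balance that was 2 higher and 7 lower when scaled by library totals, and their median of −0.16 and mean of −0.07 had the opposite sign to the list test (adjusted p = 0.826). Of 29 lists tested, 10 were called with the preset correlation and 0 with an estimated correlation. The directions of the oxidative phosphorylation, immediate-early, stromal, histone and endoplasmic reticulum lists, by members called, held under each scaling tried, as did those of the lists called with infection.

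**Figure D3:**
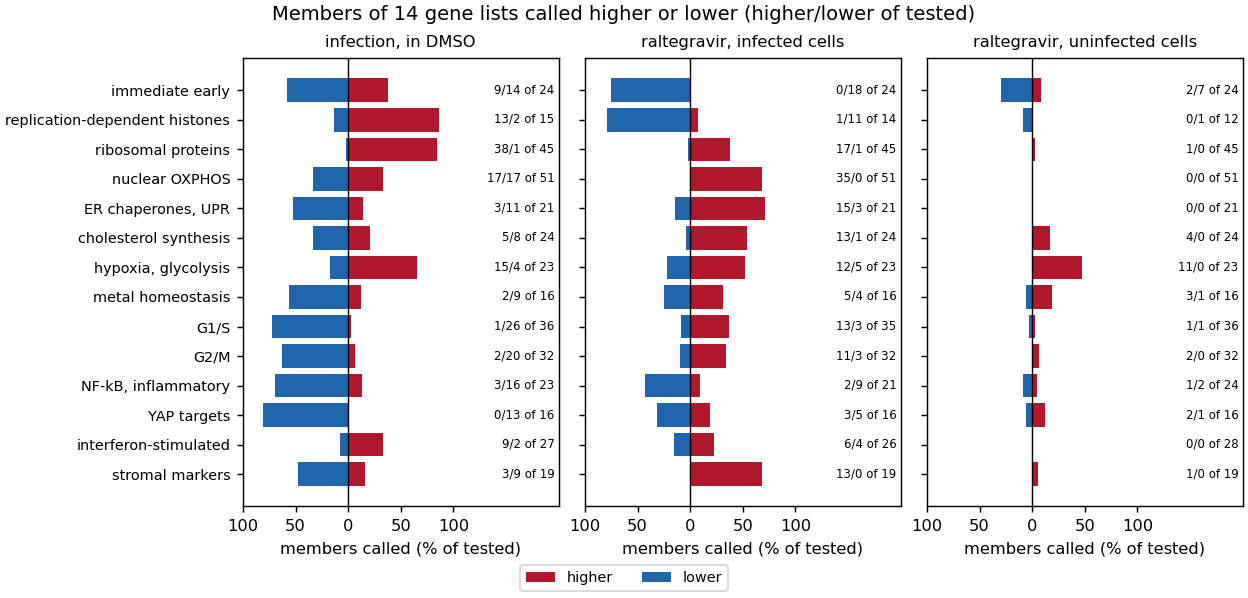
Bars give the percent of tested members of 14 gene lists called higher (right, red) or lower (left, blue) in each comparison, with the counts beside them. Oxidative phosphorylation genes had 35 of 51 members higher with raltegravir in infected cells and 0 in uninfected cells, and the balance of metal homeostasis genes in infected cells (5 higher, 4 lower) flipped to 2 higher and 7 lower when scaled by library totals.

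The effect of raltegravir differed between infected and uninfected cells for SLC30A1, HMOX1, BAX and COL1A1, among others. For SLC30A1 the difference was −2.61 ± 0.34 (adjusted p = 5.92e-05): it was at 140 ± 6.58 and 836 ± 32.6 CPM in uninfected DMSO and raltegravir cells and at 95.1 ± 54.2 and 93.1 ± 8.83 CPM in infected ones. For HMOX1 it was −4.52 ± 0.61, and −3.61 without infected DMSO replicate 1. MT3 (−2.82 ± 0.24), PFKFB3 (−2.52 ± 0.27) and ID2 (−2.27 ± 0.16) differed in the same direction. BAX differed by 1.95 ± 0.18 (adjusted p = 1.06e-05) and COL1A1 by 1.71. The other genes with the largest differences were CINP, TMEM54, PLAUR, KRT10, UROS, TIGD7, GKAP1 and ZBTB9, from 1.58 to 1.79, and CIART, ADM, RPS7, SPRY1 and ZNF276, from −2.65 to −2.02.

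Of 19494 loci tested for this interaction, 3521 had a higher and 2973 a lower effect of raltegravir in infected than in uninfected cells. Scaled on nuclear loci with a symbol alone, 1438 were higher and 1879 lower, and the higher share of 54.2% was 40.6% with DESeq2 size factors in edgeR, 41.5% with upper quartiles and 37.7% with library totals, which moved the median of all loci from 0.0365 to −0.0817, −0.0870 and −0.137. Metal homeostasis genes as a list had 3 higher and 3 lower of 16 and no call (adjusted p = 0.297). Genes of oxidative phosphorylation had 29 higher and 0 lower of 51, and 33 and 0 adjusted over the list alone (adjusted p = 3.59e-07, and 0.909 with an estimated correlation). Stromal markers had 10 higher and 0 lower of 19 by either adjustment (adjusted p = 2.85e-05, and 0.882 with an estimated correlation). Immediate-early genes had 0 higher and 11 lower of 24, and 15 lower adjusted over the list alone (adjusted p = 4.09e-05, and 0.882 with an estimated correlation). Chaperones of the endoplasmic reticulum had 10 higher and 1 lower of 21, and 12 and 1 adjusted over the list alone (adjusted p = 0.000876, and 0.909 with an estimated correlation). Genes of MHC class I presentation had 5 higher and 1 lower of 9 by either adjustment (adjusted p = 0.0096, and 0.882 with an estimated correlation). Genes of G2/M and mitosis had 11 higher and 1 lower of 32, and 11 and 2 adjusted over the list alone (adjusted p = 0.0461, and 0.909 with an estimated correlation). Genes of G1/S and replication had 11 higher and 0 lower of 36, and 9 and 0 adjusted over the list alone (adjusted p = 0.0473, and 0.909 with an estimated correlation). The calls of both cell cycle lists were lost without uninfected DMSO replicate 1 (adjusted p = 0.0506 for G2/M and 0.0701 for G1/S), uninfected raltegravir replicate 3 (0.0676 and 0.0875), infected DMSO replicate 3 (0.153 for each) or infected raltegravir replicate 2 (0.221 and 0.0887), and that of G1/S also without infected raltegravir replicate 1 (0.0549). Both calls were also lost with library totals (0.153 for G2/M and 0.136 for G1/S) and with a filter of 1 CPM in 3 libraries (0.156 and 0.134). Their ranges over all alternatives were 0.00273 to 0.221 and 0.00341 to 0.153.

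Loci raised by raltegravir in uninfected cells were more often lower than higher with the drug in infected cells. Of 662 loci raised in uninfected cells and tested in both, 348 were lower in infected cells, where independence would give 133, and 55 were higher, where it would give 175. Of 598 loci lowered in uninfected cells, 183 were lower in infected cells, against 120 under independence, and 47 were higher, against 158. The counts under independence pool all kinds of locus, although 45.1% of unannotated loci and 14.3% of loci with a symbol were lower in infected cells. Among loci with a symbol raised in uninfected cells, 150 of 356 were lower in infected cells and 51 higher. Across 14579 loci the raltegravir effects with and without infection had r = −0.129 and rho = −0.0201, and r changed sign to 0.108 over nuclear loci with a symbol. Without uninfected raltegravir replicates 1, 2 and 3 r was −0.282, −0.0415 and −0.0482, and without uninfected DMSO replicate 3 it was −0.208. These correlations are across genes, which are not independent replicates.

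Loci that infection raised in DMSO tended to be lower with raltegravir in infected cells, as for ATF3, HIST1H1B and FOS, and loci that it lowered, such as BAX, COL1A1 and HSPA5, tended to be higher. Gene lists did not all follow this. Histone genes, chaperones of the endoplasmic reticulum and stromal markers moved in opposite directions. Ribosomal protein genes had 38 higher and 1 lower of 45 with infection, and 17 and 1 with the drug. Immediate-early genes had 9 higher and 14 lower of 24 with infection, and 0 and 18 with the drug. NF-kB and inflammatory genes were also more often lower than higher in both. Among loci tested in both comparisons, 3057 were higher with infection and lower with the drug and 2461 were lower with infection and higher with the drug, while 266 were higher in both and 355 lower in both. These counts were made in the main scaling only. An error in the scale of the shared infected DMSO libraries would move loci in opposite directions in the comparisons. Loci with a symbol had medians of −0.199 with infection and 0.196 with the drug. Across 16116 loci r was −0.698 and rho −0.670. The infected DMSO libraries enter both comparisons, which by itself gives a negative r. On log2 CPM the observed r was −0.690, with the same sign at 28.6% of loci, and 20 simulations without any change gave a mean r of −0.560 (−0.578 to −0.545) with the same sign at 31.9%. The observed covariance was −0.815 and the simulated ones ran from −0.0375 to −0.0342. With infected DMSO libraries that were not shared r ran from −0.578 to −0.673 over all loci and from −0.385 to −0.491 over nuclear loci with a symbol. Infection in raltegravir changed 3405 of 16106 loci upward and 3727 downward, against 6638 and 5959 of 18284 in DMSO. The common coefficient of variation between libraries was 0.143 in the former and 0.0895 in the latter comparison. The numbers of calls therefore do not compare the size of the response. For infection in raltegravir, the higher share of 47.7% was 60.4% with upper quartiles and 28.4% with library totals, which moved the median of all loci to 0.128 and −0.218. With the replicate number as a block 8804 loci were called in place of 7132.

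**Figure D4:**
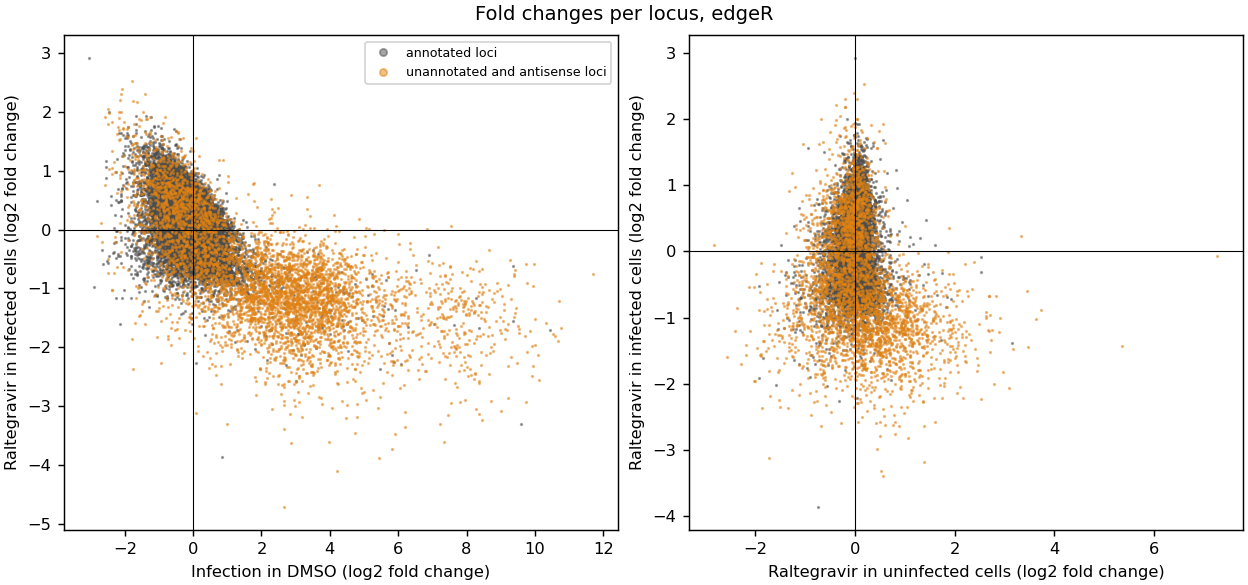
Each point is a locus, with its log2 fold change with raltegravir in infected cells on the vertical axis and that with infection in DMSO (left) or with raltegravir in uninfected cells (right) on the horizontal axis. Unannotated and antisense loci (orange) lie mostly to the right and below 0 in the left panel, and r was −0.698 on the left and −0.129 on the right, where it was 0.108 over nuclear loci with a symbol.

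Loci outside annotated genes made up much of the number of loci called higher with infection. In fragments their share was small, at 2.77% in uninfected DMSO cells and 4.69% in infected DMSO cells. Of 6359 such loci tested in DMSO, 3795 were higher and 1025 lower, with a median of 1.62, and of 412 loci antisense to genes 213 were higher and 87 lower, with a median of 0.79. With raltegravir in infected cells, 294 of 4801 unannotated loci were higher and 2165 lower, with a median of −0.89, and 36 of 353 antisense loci were higher and 137 lower. In uninfected cells 281 of 5461 unannotated loci were higher and 228 lower with the drug, and of 356 antisense loci 11 were higher and 41 lower, with a median of −0.28.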

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

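The tests of the gain of silent genes, of unannotated loci other than the 10 with the largest gain, of gains by position, and of correlations with no library shared at the smallest total and on loci with a symbol were chosen only after the result was seen, as were thinning and testing on nuclear loci with a symbol alone.

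A difference in the effect of raltegravir between infected and uninfected cells, tested as an interaction, was found at 6494 loci. Of 60 drawn splits of the libraries, 1 (the real one) gave as many, and the highest of the other splits gave 6229, with the uninfected labels exchanged. The 7 other splits that kept the infected labels gave 3166 to 6229 and the rest 0 to 3, so the count follows the drug groups of infected libraries. Splits that exchange those labels take away the drug effect itself, and those that keep them are too few for a share under 0.05, so the splits do not test whether the effect differs with infection. The mean difference was −0.65 for immediate-early genes, 0.42 for chaperones of the endoplasmic reticulum, 0.255 for G1/S genes, 0.29 for G2/M genes, 0.57 for oxidative phosphorylation, 0.48 for MHC class I presentation and 0.67 for stromal markers. For the 7 lists called, 27 of the 60 splits gave as many and the highest of the others 13, so chance is not excluded for the number of lists.

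Genes with a more positive effect of raltegravir in infected cells were BAX (1.95), CINP (1.79), TMEM54 (1.78), COL1A1 (1.71), PLAUR (1.71), KRT10 (1.70), UROS (1.67), TIGD7 (1.61), GKAP1 (1.59), ZBTB9 (1.58), APOLD1 (1.55), TGFBI (1.496), CCDC160 (1.49), ST3GAL2 (1.47), TMTC2 (1.34), C17orf80 (1.22), HAS2 (1.05) and LSM11 (1.01). Genes with a more negative effect were HMOX1 (−4.52, and −3.61 without infected DMSO replicate 1), MT3 (−2.82), ADM (−2.65), CIART (−2.65), SLC30A1 (−2.61), PFKFB3 (−2.52), ID2 (−2.27), RPS7 (−2.25), SPRY1 (−2.14), ZNF276 (−2.02), HIST1H1T (−1.92), NFKBIZ (−1.85), HIST1H1B (−1.77), SEPT4 (−1.70), DDIT4 (−1.62), PPP1R3B (−1.55), RAB3A (−1.51), HIST1H1A (−1.08) and ATF3 (−0.92). The values of FAM71A (−4.77) and NPPC (−4.22) rest on 4 and 10 counts in the 6 uninfected libraries and depend on the prior count. Fragments of RPS7 may come from another copy of that gene, which was not tested.

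With 3 libraries against 3, the 10 splits are too few for a share under 0.05. For raltegravir in infected cells the real count was 7749 loci and the highest other 0 (1 of 10 splits as large), and for lists 10 and 10 (2 of 10). For raltegravir in uninfected cells these were 1399 and 0 (1 of 10), and for lists 8 and 11 (6 of 10). For infection in DMSO they were 12597 and 0 (1 of 10), and for lists 11 and 13 (2 of 10), and for infection in raltegravir 7132 and 0 (1 of 10). The correlation of raltegravir effects with and without infection was as far from 0 in 50 of 100 pairs of splits (highest other 0.522), so chance is not excluded for it. That of raltegravir with infection effects was as low in 38 of 100 regroupings of 9 libraries (lowest other −0.963), which decides nothing, because regrouping puts the infection effect into both fold changes.

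Raltegravir in infected cells tended to move loci opposite to infection (r = −0.698). The infected DMSO libraries enter both comparisons, and simulations of this alone gave r from −0.578 to −0.545, but with none shared r nearest to 0 was −0.578 and the observed covariance of −0.815 was beyond the simulated −0.0375 to −0.0342, which argues against sharing as the whole cause. At the smallest total r was −0.698, and −0.585 nearest to 0 with no library shared, which argues against depth as the whole cause. Over nuclear loci with a symbol r was −0.494, and with no library shared it was −0.385 nearest to 0, but a shift of the scaling by mitochondrial and unannotated loci adds the same constant to each locus and leaves r as it is, so neither value tests it. The drug was added 2 h after infection, so it cannot have acted on the first 2 h. A lower or slower course of infection after that in raltegravir-treated cells may be the source, which stays open because the amount of virus is not in the files.

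Loci outside annotated genes rose with infection and fell with raltegravir in infected cells. The median change past gene ends minus that before gene starts was −2.57 (95% −2.81 to −2.33) within 10000 bp. The median gain was −0.0115 against 1.22 CPM per kb, so loci past gene ends rose less. Of 889 loci past gene ends on the gene strand 337 were higher, and of 3125 with no gene within 10000 bp 2053 were. Transcription past gene ends stays open, because transcripts joined to a gene may lie within its locus. Genes more than 10000 bp upstream of these loci were also not screened. Past gene ends the median on the gene strand minus that on the other was −0.913 (95% −1.58 to −0.513), in neither range set beforehand, and silent genes gained 1.70% (95% 1.22 to 2.42) per kb of what unannotated loci gained, but those loci were assembled where reads lie, so DNA or randomly placed reads stay open. Viral reads may account for part of the gain at the 10 loci with 35.3% of it, which cannot be told apart without the viral sequence, although 9 of them were already at 65.1 to 617 CPM in uninfected DMSO cells and 1 at 0.879 CPM, and 59.6% of the other 6349 loci were also higher, against a few loci as the whole pattern. Transcription induced at these loci by infection, which the design names, stays open.

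The 359 loci with a symbol raised by raltegravir in uninfected cells, such as SLC30A1 and HMOX1, did not rise as a set in infected cells, where 51 of 356 were higher and 150 lower. Their median change with infection was 0.105 (quartiles −0.43 and 0.71), against 0.448 with raltegravir in uninfected cells, and 153 were higher and 120 lower with infection. Among all loci with a symbol, 22.2% were higher and 42.8% lower with infection. The set was chosen by its rise over uninfected DMSO libraries, which are also the baseline of infection, so both medians can be too high. Earlier induction by infection may account for some of them, but not for the 120 that it lowered. With uninfected libraries thinned to the mean total of infected ones, 77.7% were still called, which argues against lower depth alone. Thinning does not copy the larger spread of infected libraries (common coefficient of variation 0.147, against 0.0924 in uninfected ones). A loss of calls through that spread stays open for the 155 loci without a call in infected cells. A changed response of infected cells to the drug, or the different time from starvation to collection, stays open and was not tested.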

How the results depend on the processing

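Scaling and testing without mitochondrial loci, on nuclear loci with a symbol alone, and with libraries thinned to the smallest total were chosen only after the data were seen. In log2 FPKM the interaction and both infection comparisons were not run, because the authors scaled the tables separately. Small changes were often not found: at 1.5-fold, 25.4% of simulated changes were found for raltegravir in infected cells, 49.3% for infection in DMSO and 5.97% for the interaction. At the smallest total 7240 loci were called for raltegravir in infected cells in place of 7749, and 840 in uninfected cells in place of 1399.

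For raltegravir in infected cells, 7749 loci became 5164 with log2(FPKM + 0.1), 4088 with log2(FPKM + 1) and no filter, and 4222 on nuclear loci with a symbol alone, where fewer loci were tested. Leaving out a library gave 4887 (infected DMSO replicate 3) to 7983. For raltegravir in uninfected cells, 1399 loci became 2153 with a replicate block, 218 and 162 with FPKM and a pseudocount of 1 or 0.1, 25 with FPKM and no filter, 897 with all 12 libraries in 1 fit, 775 on loci with a symbol and 840 when thinned. Leaving out a library gave 433 (uninfected raltegravir replicate 3) to 2820 (uninfected raltegravir replicate 2), with 686, 477 and 490 without uninfected DMSO replicates 1, 2 and 3. Except for the loci with a symbol and thinning, which reduce the loci tested or the depth, the cause was not tested.

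On loci with a symbol alone the interaction fell to 3317 loci and infection in DMSO to 6449, again with fewer loci tested. Leaving out a library gave 4553 to 6886 for the interaction, 11813 to 13709 for infection in DMSO and 5620 to 7494 for infection in raltegravir. The number of lists called with an estimated correlation was 0 in place of 10 and 8 for raltegravir in infected and uninfected cells, 11 for infection and 7 for the interaction. Leaving out a library gave 8 to 12, 6 to 9, 9 to 13 and 5 to 10 lists in the same order.

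The correlation of raltegravir effects with and without infection, −0.129, was −0.0341 with at least 1 CPM in 3 libraries, −0.0187 when thinned and, reversed, 0.108 on nuclear loci with a symbol, so its sign rests on the other loci. It ran from −0.282 without uninfected raltegravir replicate 1 to −0.0415 without uninfected raltegravir replicate 2, with −0.208 without uninfected DMSO replicate 3 and −0.0482 without uninfected raltegravir replicate 3. That of raltegravir with infection effects was −0.494 on loci with a symbol and −0.727 to −0.673 when a library was left out. The cause of the other shifts was not tested.

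Of 208 results for named genes, all kept their direction and side of the threshold with DESeq2, limma-voom, DESeq2 size factors, upper quartiles, a filter of 1 CPM, without mitochondrial loci and on loci with a symbol. With all 12 libraries in 1 fit 4 lost their call, with library totals 2 and when thinned 2. With no filter on low counts 2 gained a call, and with the replicate block 2. When a library was left out, 1491 gene results were on the same side, 34 lost their call and 5 gained one. Log2 FPKM was run only for raltegravir in infected and in uninfected cells, so it covers fewer of these results. With a pseudocount of 1, 18 lost their call and 85 were on the same side. With 0.1 these numbers were 22 and 81, and with no filter 42 and 62.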

Other observations

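The odds ratio for neighbours of silent genes was a test chosen only after the result was seen, and the loci named here were chosen after their values were seen.

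FAM71A, which had 0 counts in uninfected DMSO cells, lies 1724 bp past the end of ATF3 on the same strand of chromosome F1, and both were higher in infected cells. A hypothesis was that genes silent in uninfected cells gain counts because transcription may enter from an expressed gene on the same strand. Of silent genes beside an expressed gene on the same strand within 10000 bp, 16.6% (45 of 271) gained counts, against 10.3% (21 of 204) beside one on the other strand and 3.11% (28 of 901) beside a silent gene. The odds ratio of the same against the other strand was 1.73 (95% 0.971 to 3.18, two-sided Fisher's exact p = 0.0602, and adjusted p = 0.0602 over the 2 comparisons made), which leaves the hypothesis undecided. Against a silent neighbour it was 6.20 (two-sided Fisher's exact p = 2.99e-13, adjusted p = 5.97e-13).

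An unannotated locus on an unplaced scaffold had 33, 20 and 15 counts in uninfected DMSO libraries, 35, 48 and 7 in uninfected raltegravir libraries, 6969, 7333 and 6304 in infected DMSO libraries and 6087, 4780 and 4879 in infected raltegravir libraries.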
